A study of Homo sapiens with 4 samples.

How the data were processed

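RNA sequencing measured gene expression in NCI-H520, an established lung squamous cell carcinoma cell line, in 2 libraries from cells given ultrapure water (Vehicle) and 2 libraries from cells given 10 µM Hx1R8 for 12 h. Per the labels' protocols, the cells were grown in RPMI-1640 with 15% fetal bovine serum, total RNA was taken with TRIzol, and 1.5 µg of it went into each library, made with the ABclonal Fast RNA-seq Lib Prep Kit V2. What Hx1R8 is made of is not given in the sources used here.

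The authors deposited a table of raw counts per gene with 1 column per library, and per the submitters' processing notes the reads were aligned with STAR 2.7.9 to hg38. The counting tool, the gene annotation and the strand setting are not given in the sources used here. The deposited table also lists exon coordinates, strand and a summed exon length for each gene, per the file headers, and coordinates are printed as listed there, on hg38. Where the counting left out reads that fall on more than 1 gene, a gene with overlapping neighbours was counted on the remaining bases only, and without a stated strand setting a gene and an antisense neighbour cannot be separated. The table held 28277 genes after 2 lines that hold 1 gene's broken row, with no reads, were left out. Rows naming no gene held 0 reads.

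Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with TMM factors, the filterByExpr filter and group as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter kept 14482 genes. CPM values were scaled by the TMM factors, which lay between 0.998 and 1.00. Standard errors and 95% intervals of log2 fold changes came from the fitted model. Of 37 gene lists, the 35 with at least 5 tested members were tested with camera of limma 3.58.1. Camera was run on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01. Of 1081 list entries, 1067 matched a gene in the table, some through synonyms of the RefSeq table of GRCh38.p14, and 14 did not. The 13 mitochondrially encoded genes were among those without a match and were not analysed here.

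The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took SOX2, the 12 largest rises and the 12 largest falls among genes past the threshold with a mean log2 CPM of at least 2, both Hx1R8 libraries on the same side of both Vehicle libraries and a named symbol, and up to 4 members of each list by smallest adjusted p. Housekeeping genes and markers of other cell types were described by counts and by their 4 most abundant members. The text names a part of the list members the rule took. KRT5, KRT6A, TP63, NKD1, EEF1A1, CXCL14, SFTPA1, DERL3, BMP6, BLOC1S5-TXNDC5, RNA45SN2, RNA28SN2 and the genes named for single libraries or other groupings of the libraries were chosen after the data were examined.

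Total counts were 17483349 and 17352323 in Vehicle replicates 1 and 2 and 17259403 and 20920857 in Hx1R8 replicates 1 and 2. A floor of 3 counts corresponded to 0.143 to 0.174 CPM, which covers counting error only. No 2 libraries agreed within sampling noise (chi-square per gene 1.48 to 2.95, highest between the 2 Vehicle libraries), so none was taken for a copy of another. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. The test was checked on simulated counts for this comparison over 14343 genes, in which it called 55.1% of 1.2-fold, 69.4% of 1.5-fold, 91.8% of 2-fold and 100% of 4-fold changes, together with 10 unchanged genes. With no change simulated it called 0 of 14350 genes, with 682 at an unadjusted p under 0.05. The simulated counts held no differences shared by many genes of a single library, so these rates need not hold for the real counts. In simulated counts with 2 lists shifted by 1.1-fold, camera called both and none of the 33 other lists. Simulated genes varied independently of one another, so false list calls from correlated genes could not show there. In the real counts the estimated inter-gene correlation of the cytosolic ribosomal protein genes was 0.40.

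Alternatives covered median-ratio and upper-quartile factors, library totals alone, no low-count filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, robust dispersions, the replicate number as a block, leaving out each library in turn and leaving out the 1 row with an exon on the mitochondrial chromosome. Lists were also tested with an estimated correlation, with fry, with the block and with each library left out. Offsets per library for exon length and for the GC content of each gene's longest GENCODE v29 transcript (spline with 4 degrees of freedom) were added after seeing the data, as were fry's test for change in either direction and camera with an estimated correlation with each library left out.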

Results

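The transcriptome of NCI-H520 cells, a lung squamous cell carcinoma line, was compared between 2 libraries from water-treated cells (Vehicle) and 2 libraries from cells exposed to 10 µM Hx1R8 for 12 h. The series concerns the self-association of SOX2, a lineage transcription factor of squamous lung cancer, and drug resistance. The comparison asks which transcripts differ after Hx1R8. Total counts ranged from 17259403 to 20920857 per library, and 14482 genes were tested.

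In untreated cells SOX2 was far more abundant than TP63, KRT5 and KRT6A. SOX2 was abundant at 528 ± 18.7 CPM (SD, n = 2), whereas TP63, the squamous lineage factor, was at 0.431 ± 0.044 CPM and the basal keratin KRT5 at 1.67 ± 0.34 CPM in Vehicle (SD, n = 2). KRT6A, a stress-associated keratin, was at 19.8 ± 0.12 CPM in Vehicle (SD, n = 2). Among neuroendocrine and neuronal markers, CHGB (a secretory granule protein) reached 526 ± 2.18 CPM, UCHL1 289 ± 2.55 CPM and POU3F2 156 ± 1.47 CPM in Vehicle (SD, n = 2). FOXA2 was at 127 ± 5.74 CPM and NKX2-1, the lung lineage factor, at 11.7 ± 1.61 CPM in Vehicle (SD, n = 2). By mean CPM over all libraries EEF1A1 stood first, followed by NKD1, a WNT pathway inhibitor, and CXCL14 stood at rank 7. In Vehicle they were at 12649 ± 408, 4455 ± 218 and 3343 ± 119 CPM (SD, n = 2). CPM is not divided by exon length, so this order is one of reads and not of transcript numbers. NKD1 has 17039 exon bases, against 3512 for EEF1A1 and 1685 for CXCL14. Of 18 immune cell markers, 16 were below 1 CPM in both groups, as were 13 of 18 fibroblast and endothelial markers, 12 of 20 alveolar markers and 8 of 20 neuroendocrine markers.

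SOX2 transcript levels did not differ detectably between the groups. SOX2 (chromosome 3, 181711925 to 181714435, its exon shared with no other listed gene) was at 528 ± 18.7 CPM in Vehicle and 510 ± 17.4 CPM in Hx1R8 (SD, n = 2 each). The log2 fold change was -0.05 (SE 0.05, adjusted p = 0.9999), and the 95% interval of the fold ran from 0.905 to 1.03.

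Across the transcriptome, 2 genes rose and 1 gene fell after Hx1R8. TXNDC5, a protein disulfide isomerase of the endoplasmic reticulum, rose 3.38-fold, from 2.64 ± 0.14 to 8.90 ± 1.25 CPM (SD, n = 2 each). RNA28SN5, a copy of the 28S ribosomal RNA gene, rose 2.87-fold, from 2.71 ± 1.97 to 7.72 ± 0.89 CPM (SD, n = 2 each). IFI27, an interferon-inducible gene, fell to 0.753 of its Vehicle level, from 254 ± 6.77 to 192 ± 19.4 CPM (SD, n = 2 each). Both rises exceeded 2-fold and no fall did.

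**Figure D1:**
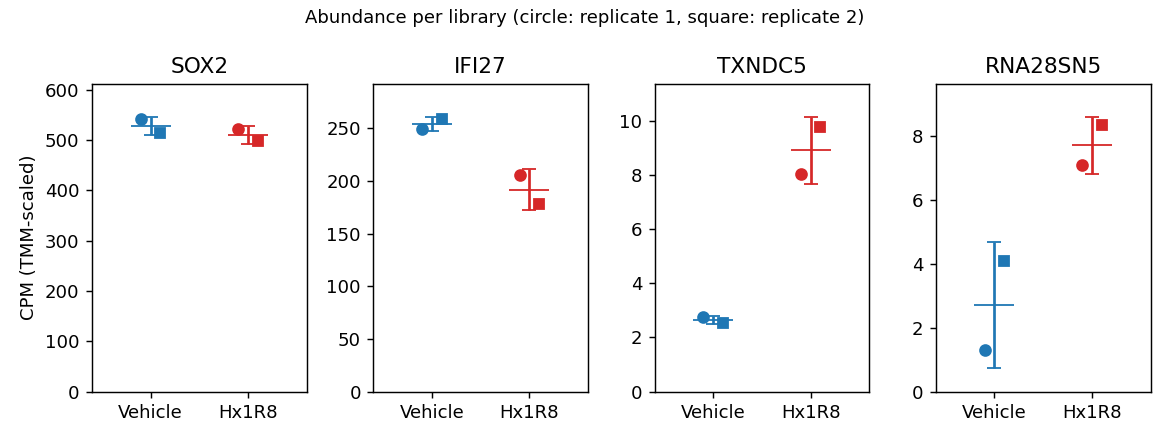
TMM-scaled CPM of SOX2, IFI27, TXNDC5 and RNA28SN5 in each library of the Vehicle and Hx1R8 groups, with the group mean as a dash and 1 SD as the error bar (n = 2 each). SOX2 lies near 528 CPM in Vehicle and 510 CPM in Hx1R8, TXNDC5 rises from 2.64 to 8.90 CPM, and the Vehicle libraries of RNA28SN5 lie apart at 1.31 and 4.11 CPM.

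By edgeR's quasi-likelihood test, the log2 fold change of TXNDC5 was 1.76 (SE 0.18, adjusted p = 8.3e-09), with read counts of 48 and 44 in Vehicle and 138 and 205 in Hx1R8. TXNDC5 lies on chromosome 6 (7881514 to 7910788), where 16.8% of its 3206 exon bases belong to no other listed gene, the rest being shared with BLOC1S5-TXNDC5 or BMP6. IFI27 (chromosome 14, 94110736 to 94116690) had a log2 fold change of -0.41 (SE 0.05, adjusted p = 1.3e-05), with both Hx1R8 libraries below both Vehicle libraries. Without Hx1R8 replicate 2 the log2 fold change of IFI27 was -0.31 and the call was lost (adjusted p = 0.337), within a range of adjusted p from 3.7e-23 to 0.337 over its alternatives. RNA28SN5 had a log2 fold change of 1.52 (SE 0.23, adjusted p = 9.6e-05), and 6.95% of its exon bases belong to no other listed gene, so its reads are uncertain among the copies of the ribosomal RNA genes. Its Vehicle counts of 23 and 71 differed by 3.12-fold in CPM. Its call was lost with DESeq2 and with robust dispersions (adjusted p = 0.99999 and 0.9999), at log2 fold changes of 1.51 and 1.52. The log2 fold change was 0.92 without Vehicle replicate 1 and 2.56 without Vehicle replicate 2.

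**Figure D2:**
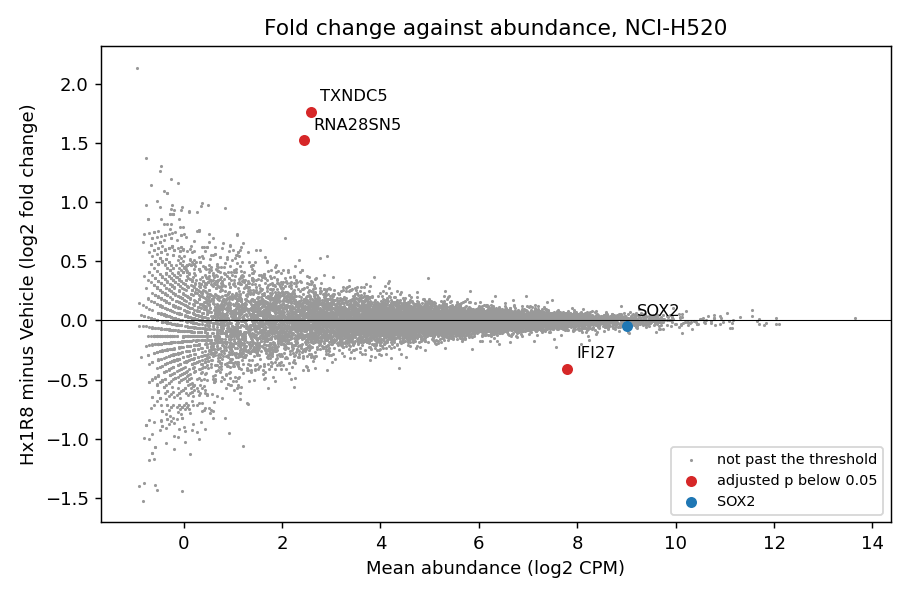
Log2 fold change of Hx1R8 over Vehicle against mean log2 CPM for each of the 14482 tested genes, with genes at an adjusted p below 0.05 in red and SOX2 in blue. The 3 genes past the threshold are TXNDC5 and RNA28SN5 above 0 and IFI27 below 0, and SOX2 lies at -0.05.

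For most genes the 95% intervals were narrow, though they bound only the difference between these libraries. They rest on 2 residual degrees of freedom, with 36.9 prior degrees of freedom added from the spread of all genes. Leaving out a Vehicle library moved RNA28SN5 outside its own interval. The 95% interval lay within 1.5-fold of no change for 81.4% of tested genes, and within 1.2-fold for 98.2% of the 6407 genes above 32 CPM, whereas below 4 CPM 19.5% of genes were bounded within 1.5-fold. At an unadjusted p under 0.05 there were 491 genes, against 724 expected with no effect. In 29.8% of genes both Hx1R8 libraries lay outside the Vehicle range on one side, against 33.3% for 4 libraries in random order. The number of genes called depended on single libraries: it was 79 without Vehicle replicate 1 and 31 without Vehicle replicate 2, against 7 without Hx1R8 replicate 1 and 6 without Hx1R8 replicate 2.

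Gene programmes linked to SOX2 and to squamous identity had no member past the threshold. Of 24 tested squamous lineage genes none passed, and the smallest unadjusted p values belonged to SFN (log2 -0.22, SE 0.08), PITX1 (0.12, SE 0.05) and DSC3 (0.31, SE 0.14). None of 18 stemness genes passed, with SALL2 at -0.08 (SE 0.07), and none of 15 other SOX and partner factors, with SOX21 at 0.13 (SE 0.06) and SOX14 at -0.23 (SE 0.13). Of 21 coactivator and condensate genes none passed, with the histone demethylase gene KDM6A at -0.32 (SE 0.18) and AFF4 at 0.06 (SE 0.05). None of 8 keratinocyte differentiation genes passed, with the desmosomal cadherin DSC2 at 0.09 (SE 0.08). Only 3 of these 8 had intervals within 1.5-fold of no change, and their values ran from -0.53 to 0.67. Within 1.5-fold were also 17 of the 24 squamous genes, whose values ran from -0.36 to 0.90, and 12 of the 18 stemness genes. The same held for 13 of the 15 other SOX and partner factors and 20 of the 21 coactivator and condensate genes. Tested for change in either direction with fry, chosen after seeing the data, the other SOX and partner factors (adjusted p = 0.013), the squamous list (0.023) and the interferon list (0.045) were called, against 0 and 5 lists when the 4 libraries were grouped 2 against 2 in the other 2 ways. Camera called none of these 3 lists, with the preset correlation (adjusted p of 0.758 or more) or an estimated correlation (0.938 or more). Camera tests for a shift in a single direction, so it cannot decide on members that change in both directions.

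Drug response and stress programmes likewise had no member past the threshold over all genes. Of 17 drug efflux transporters 15 had intervals within 1.5-fold of no change, ABCC2 was at 203 CPM in Hx1R8 against 213 CPM in Vehicle (log2 -0.07, SE 0.05), and ABCC6 had the lowest value at -0.54 (SE 0.24). Camera did not call the transporters (adjusted p = 0.758), while fry, which does not compare a list with other genes, gave an adjusted p of 0.024 for a shift downwards with a median log2 fold change of -0.0043. All 35 DNA damage repair genes were bounded within 1.5-fold, among them RAD51C (0.16, SE 0.07) and XRCC3 (-0.11, SE 0.06). None of 26 p53 targets passed, with BAX at -0.09 (SE 0.07) and TP53INP1 at 0.22 (SE 0.15). In the integrated stress response list of 32 tested genes, CEBPB was highest at 0.37 (SE 0.13) and DDIT4 was at -0.14 (SE 0.09). Of these 32, 27 were below 0 and 5 above, with a median of -0.02. Of 27 unfolded protein response genes 26 were bounded within 1.5-fold, including the chaperone PDIA3 (0.06, SE 0.05) and XBP1 (0.10, SE 0.06). None of 19 heat shock genes passed over all libraries, with HSPA1B at 0.25 (SE 0.08) and HSPD1 at 0.08 (SE 0.05). HSPA1B passed without Hx1R8 replicate 2 (0.45), which left Hx1R8 replicate 1 at 49.2 CPM. Hx1R8 replicate 2 was at 37.4 CPM, near the 35.7 and 36.5 CPM of Vehicle. HSPD1 passed without Vehicle replicate 1 (0.13), where the only control was Vehicle replicate 2, the library that differed most from the others. None of 29 NRF2 targets passed, with UGDH at -0.12 (SE 0.06) and FTL at -0.07 (SE 0.05), and none of 6 metallothionein list members, with MT2A at -0.09 (SE 0.09).

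Replication and mitotic genes were closely bounded, and histone genes were not. All 40 DNA replication and G1/S genes and all 44 mitotic genes had intervals within 1.5-fold of no change, with E2F2 at -0.12 (SE 0.06), TYMS at 0.12 (SE 0.06), AURKB at -0.11 (SE 0.06) and KIF11 at 0.07 (SE 0.05). None of 30 apoptosis regulators passed and 27 were bounded within 1.5-fold, with the anti-apoptotic BCL2L1 at -0.08 (SE 0.05) and BIRC5 at -0.07 (SE 0.05). Of 6 tested replication-dependent histone genes none passed, 0 were bounded within 1.5-fold and 3 within 2-fold, with H2BC12 at 0.33 (SE 0.17).

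Among signalling programmes only the interferon list held a called gene. IFI27 was the 1 of 30 tested interferon response genes past the threshold, and the other 29 were not, among them IRF9 at 0.18 (SE 0.11) and IFIT2 at -0.63 (SE 0.35). Of the 29, 21 had 95% intervals above the fall of IFI27, among them all 13 above 10 CPM. None of 32 immediate early genes passed, with JUNB at -0.17 (SE 0.08), and none of 21 NF-kB and cytokine genes, with CXCL3 at 0.62 (SE 0.25) and IL32 at -0.38 (SE 0.19). In the WNT list of 21 tested genes LGR6 was at -0.13 (SE 0.06) and AXIN2 at -0.04 (SE 0.05). Of 21 NOTCH pathway genes none passed over all libraries, with HES1 at 0.17 (SE 0.06), which passed without Vehicle replicate 1 (0.23). In that setting the only control was Vehicle replicate 2, the library that differed most from the others. None of 19 YAP and TEAD targets passed, with TGFB2 at 0.09 (SE 0.05), and none of 22 epithelial-mesenchymal transition genes, with SNAI1 highest at 0.76 (SE 0.35). Of these 22, 17 were below 0 and 5 above, with a median of -0.04.

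Metabolic genes and the translation machinery varied by small amounts. Cytosolic ribosomal protein genes were the 1 list of 35 that camera called, shifted downwards with a median log2 fold change of -0.04 over 78 members, 65 of them below 0 (adjusted p = 0.013). The call was lost with an estimated correlation (adjusted p = 0.938), without Vehicle replicate 2 and without Hx1R8 replicate 2, where camera's direction turned upwards (unadjusted p = 0.638), and no member passed over all genes. With the 4 libraries grouped 2 against 2 in the other 2 ways, camera also called 1 list each, and 0 with an estimated correlation. Vehicle replicate 1 with Hx1R8 replicate 2 against the rest gave the ribosomal genes at an adjusted p of 0.00014 (with an estimated correlation, unadjusted p = 0.35). The median log2 difference of Hx1R8 replicate 2 from the other 3 libraries was -0.08 for this list. RPL41 had the smallest unadjusted p in the list (log2 -0.20, SE 0.05, adjusted p = 0.25). The log2 fold changes of RPS27 (-0.22, SE 0.07) and RPL38 (-0.20, SE 0.07) went to 0.0013 and 0.0021 without Hx1R8 replicate 2. RPS27 passed without any other single library (-0.47 to -0.18), and RPL38 without Vehicle replicate 2 (-0.23) and without Hx1R8 replicate 1 (-0.42). RPL41 passed without Vehicle replicate 1 (-0.22) and without Vehicle replicate 2 (-0.18). None of 49 nuclear oxidative phosphorylation genes passed over all libraries, with UQCRQ at -0.17 (SE 0.06) and COX6B1 at -0.17 (SE 0.06), the latter passing without Vehicle replicate 1 (-0.24), and camera called this list downwards without Hx1R8 replicate 1 (adjusted p = 0.046), a call lost with an estimated correlation (0.992, chosen after seeing the data). Camera also called it for Vehicle replicate 1 with Hx1R8 replicate 1 against the rest (adjusted p = 0.0075; with an estimated correlation, unadjusted p = 0.16). Of 28 hypoxia and glycolysis genes none passed over all libraries, with the glycolytic enzyme PGAM1 at -0.16 (SE 0.05), which passed without Vehicle replicate 1 (-0.17). For PGAM1 and the genes above, that setting left Vehicle replicate 2, which differed most from the other libraries, as the only control. All 26 cholesterol and all 15 fatty acid synthesis genes were bounded within 1.5-fold, with EBP at -0.11 (SE 0.06) and SCD at 0.05 (SE 0.05). All 35 lysosome and autophagy genes and all 40 ribosome biogenesis and MYC targets were also bounded within 1.5-fold, with ASAH1 at 0.13 (SE 0.06) and MRTO4 at -0.11 (SE 0.05).

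**Figure D3:**
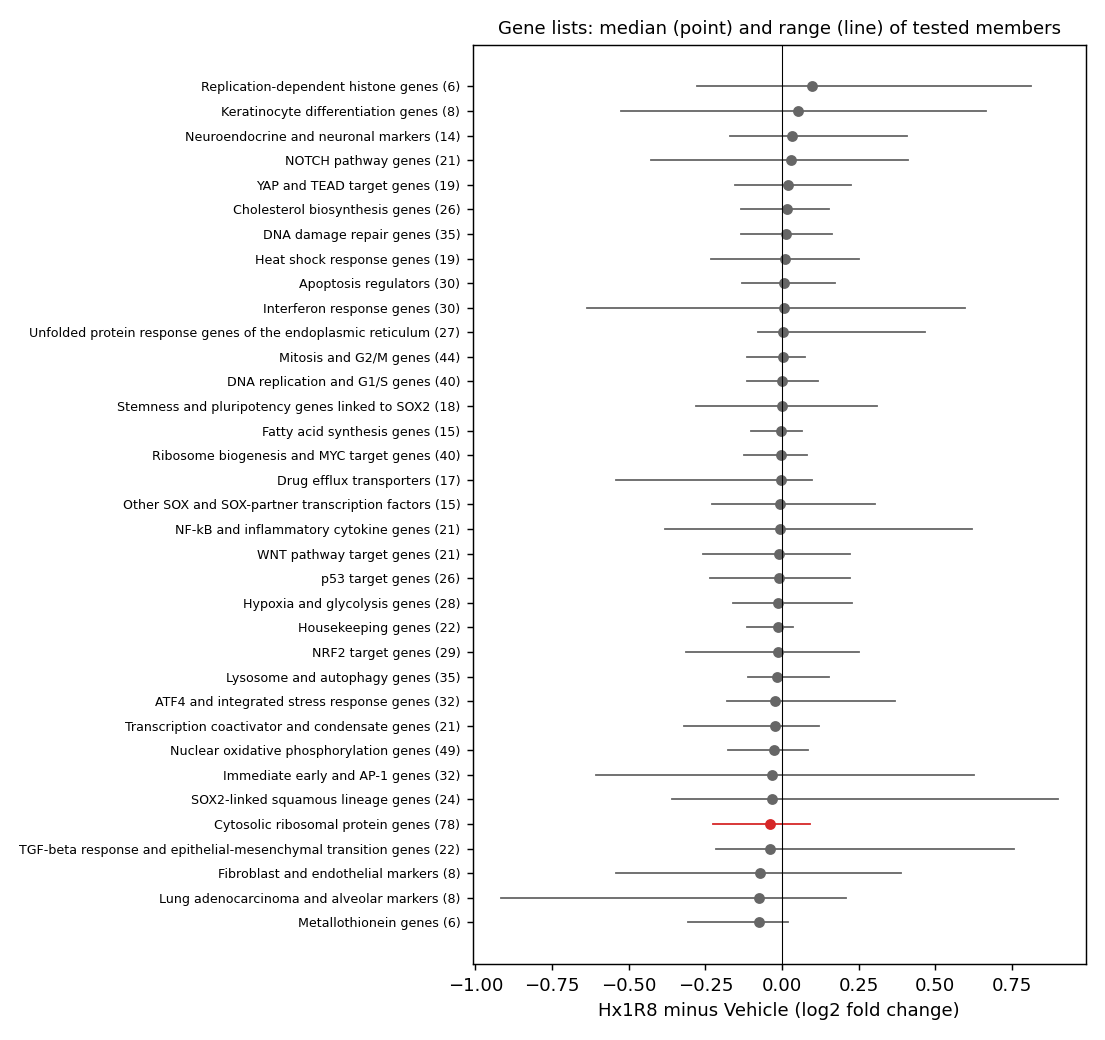
Median log2 fold change (point) and range (line) of the tested members of each of 35 gene lists, Hx1R8 over Vehicle, with the number of members in brackets and the list called by camera in red. List medians lie between -0.08 and 0.10, and the cytosolic ribosomal protein genes lie at -0.04.

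Markers of other cell types and housekeeping genes had no member past the threshold. All 22 housekeeping genes were bounded within 1.2-fold, with ACTB at -0.02 (SE 0.05), whose sign turned without Vehicle replicate 2, and TFRC at 0.03 (SE 0.05). None of 14 neuroendocrine markers passed, with CHGB at 0.01 (SE 0.05), and none of 8 alveolar markers, with FOXA2 at -0.07 (SE 0.05). COL1A1, the most abundant of 8 tested fibroblast and endothelial markers, was at -0.08 (SE 0.13), and of 4 tested immune markers, too few for the list test, CD14 was at -0.37 (SE 0.32). Adjusted over the list alone, 4 lists had 1 member each past the threshold, all lower in Hx1R8: IFI27, PGAM1, RPL41 and the surfactant gene SFTPA1 (log2 -0.92, SE 0.32). The lowest camera adjusted p among the 34 lists not called was 0.19, for the alveolar markers.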

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

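TXNDC5, IFI27 and RNA28SN5 were the 3 genes called under 8 of the 10 alternatives fixed beforehand that kept all libraries. DESeq2 and robust dispersions each gave 1 gene higher, also 1 by 2-fold or more, with RNA28SN5 lost and the cause not tested. Leaving out 1 library, with the lone sample assumed to vary like the other group, gave 2 to 41 genes higher, 1 to 38 lower and 0 to 2 lower by 2-fold or more, and 0 to 2 gene lists called. TXNDC5 stayed called in all of these, at 1.597 to 1.89. SOX2 ranged from -0.08 to -0.01 with each library left out and was never called. With the replicate number as a block, 2 genes were higher and 1 lower, and camera called 1 list; the samples share only a number, and same-numbered deviations correlated at 0.03 across genes. An estimated correlation left 0 lists, and fry called 1, the efflux transporters instead of the ribosomal genes. Chosen after seeing the data, fry's test for change in either direction called 3 lists, camera with an estimated correlation and 1 library left out called 0, a GC offset gave 2 genes lower, RPL41 being added, and without Vehicle replicate 1 the GC offset gave 19 higher, 19 lower and 2 lower by 2-fold or more. In that last setting the sign turned, with no call and the cause not tested, for SOX2 (0.014), AXIN2 (0.0061), FOXA2 (0.041), NKX2-1 (0.117) and UCHL1 (0.012), and with the GC offset alone for ACTB (0.0012). With 1 library left out, signs also turned for RPS27 (-0.47 to 0.0013), RPL38 (-0.42 to 0.0021), NKX2-1 (-0.21 to 0.065), POU3F2 (-0.035 to 0.0016) and ACTB (-0.085 to 0.045). Of 1088 recomputed values of 64 named genes, 12 changed sign. Below 4 CPM, 68.9% of genes were bounded within 2-fold, so depth limits statements on scarce transcripts.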

Other observations

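The tests for sequencing depth, RNA28SN5, the read-through gene and the unfolded protein response were written after the value that decides each was seen. Those for length, GC content and BMP6 were also chosen after the main comparison was seen, but written before the value that decides each. Other groupings of the 4 libraries gave as many or more genes when no GC offset was used. Vehicle replicate 1 with Hx1R8 replicate 1 against the rest gave 10 genes, led by the short ribosomal protein gene RPL39 and the splicing factor gene SNRPG, and Vehicle replicate 1 with Hx1R8 replicate 2 gave 11, led by the tubulin gene TUBB2B and by CHORDC1, against 3 for the study's groups. With 3 such splits a share under 0.05 cannot be reached. With the GC offset the counts were 9, 3 and 4, in the same order. Genes called at 2-fold or more without an offset were 1, 0 and 2, again in that order. Each library set against the other 3, with the lone library assumed to vary like the 3 others, gave 3 genes for Vehicle replicate 1, 21 for Vehicle replicate 2, 6 for Hx1R8 replicate 1 and 9 for Hx1R8 replicate 2. Hx1R8 replicate 2 had lower RPS27, RPS29, RPL38, RPL37A and IFI27 (log2 -0.42, SE 0.07), Vehicle replicate 1 lower RNA28SN5 (-2.32, SE 0.37), and Hx1R8 replicate 1 higher CKMT1B and HSPA1B.

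Vehicle replicate 2 had the most genes under that assumption, 21, among them lower PRDX1 and BZW1 and higher TUBB2B and CST1. Its total count was 101% of that of the nearest library, which argues against depth, and an offset for exon length left more genes, 43, which argues against length. An offset for GC content left 6 genes, all among the 21, and the median absolute log2 difference of the 21 went from 0.25 (median SE 0.05) to 0.18 (median SE 0.04), so that calls ended because differences shrank. Most of these calls lay close to the threshold without an offset, so a small shrinkage could end them. A GC-dependent difference in library preparation may account for part of the difference of Vehicle replicate 2. The same offset raised the calls for Hx1R8 replicate 2 from 9 to 20, and no biological explanation was tested, since no label separates the Vehicle libraries.

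The rise of TXNDC5 could reflect other genes at its locus. BMP6, which overlaps it, was at 0.28 on the log2 scale with an upper 95% bound of 0.57, below the lower bound of 1.39 for TXNDC5, which argues against reads from BMP6. Of 27 unfolded protein response genes, 1 (DERL3, near 1 CPM) had an interval reaching a 1.5-fold rise, which argues against a response across that list. The read-through gene BLOC1S5-TXNDC5 held 0 reads in Vehicle and 0 and 2 in Hx1R8, against 251 reads gained by TXNDC5. It has 0 exon bases of its own, and how the counting shared reads between these genes is not given. The reads of the read-through gene therefore cannot decide whether reads moved between them. Where reads on shared bases were left out, the TXNDC5 count rests on its 540 own bases. The rise then holds for those bases and is not shown for the whole gene. An effect of Hx1R8 on TXNDC5 itself stays open as a hypothesis. Quantitative PCR in further cultures, of the TXNDC5 bases shared with no other listed gene and of its other bases, would test it.

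The rise of RNA28SN5 may reflect differing carry-over of ribosomal RNA between libraries. The log2 ratio between the 2 Vehicle libraries, 1.64, was as large as that between the groups, 1.52, as this explanation needs, although it does not show where the reads came from. RNA28SN2, another copy, had 1 and 2 reads in Vehicle and 7 and 10 in Hx1R8. It has 0 exon bases of its own, so its reads are likewise uncertain among the copies. More ribosomal RNA precursor after Hx1R8 stays open, since RNA45SN2, with an upper 95% bound of 0.81, held 83 reads in all. An effect of Hx1R8 on ribosomal RNA was not tested otherwise.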
